A study of Mus musculus with 2 samples.

How the data were processed

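Small-intestinal innate lymphoid cells (ILCs) of female C57BL/6 mice were sorted by flow cytometry and profiled as single cells on the 10x Genomics Chromium platform with version 2 of the 3-prime kit, and sequenced on an Illumina NextSeq, per the labels' protocols. The labels give 1 library of wild-type mice (WT, both Batf alleles floxed, no Cre) and 1 library of conditional knockout mice (cKO, both Batf alleles floxed, with a Cre recombinase driven by Plzf, the gene also named Zbtb16). They name the cells group 3 ILCs. The sort gate, the number of mice per library and the deleted Batf exons are not given in the sources used here.

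The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger on mm10 per the submitters' processing notes. The file headers give software version 3.0.0. Each row pairs an Ensembl identifier with a symbol, and all 31053 rows were the same in both libraries. The lowest barcode in each file had 500 UMIs, and the rule by which the authors called barcodes as cells is not given in the sources used here. Gene positions are those of GENCODE M21 on GRCm38, the assembly that mm10 names, in which 30934 of the 31053 identifiers had a position.

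Counts were read with scanpy 1.11.5 in Python 3.11.15. Barcodes with at least 500 detected genes and under 10% of UMIs from mitochondrial genes were kept, which left 736 of 1153 barcodes (63.8%) in the WT library and 5730 of 6443 (88.9%) in the cKO library. Scrublet, run on each library alone, called 5 WT (0.679%) and 98 cKO barcodes (1.71%) as doublets, and these were removed. The analysis went on with 731 WT cells holding 2738945 UMIs and 5632 cKO cells holding 20668437 UMIs. Median depth of the kept cells was 3813 UMIs in WT and 3632 in cKO.

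Both libraries were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering was run at resolution 0.8 on 15 neighbours. A cluster was named X-like from marker lists fixed before the data were examined. A marker counted as present at 50 CPM or more and at 0.25 or more of its level in the highest cluster. The leading class needed 3 or more markers and a share of at least 0.25 of its list, and the next class had to stay under 0.75 of that share. A mixed cluster that failed was clustered again on its own at resolution 0.5. These naming thresholds were set after the data were seen, and 34 cells (3 WT and 31 cKO) stayed unnamed under them.

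With 1 library per group there is no test across samples, no p-value and no replicate check. UMIs of all cells of a class were summed per library and expressed as counts per 1000000 UMIs (CPM). Levels have exact Poisson intervals, shares have exact Clopper-Pearson intervals, and the log2 ratio of cKO over WT CPM has an exact interval from the conditional binomial distribution, each at 95%. These intervals cover counting error only. They leave out differences between mice, sorts and library preparations, so every comparison is between 2 libraries. The intervals of levels and ratios also treat each UMI as independent and leave out differences between cells of a library. They are too narrow where few cells carry most UMIs of a gene. A gene was past the size rule when it had at least 20 CPM in 1 or both libraries and its interval lay wholly beyond 1.5-fold. The rule describes size and is no test. Mitochondrial genes, Xist and Tsix stayed in totals and out of these counts.

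The rule for named genes was fixed at the same time. It takes the 12 genes past the size rule in each direction whose interval bound lay farthest from no change in ILC3-like cells, leaving out mitochondrial, ribosomal protein, Gm-numbered and Rik-named genes and genes that changed sign in all kept cells. To these the rule adds Batf, Zbtb16, 2 to 4 members of each gene list with the farthest bounds, and Il22, Il17a, Il17f, Ifng, Tbx21, Gata3, Ncr1, Ccr6, Kit and H2-Ab1. The 12 leading genes per direction of ILC2-like cells were taken after the data were seen. The same rule was used, except that genes that changed sign in all kept cells were not left out. Where other members of a list are named, they are members past the size rule.

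For 18 gene lists fixed beforehand, the median log2 ratio was taken over members of at least 5 CPM in 1 or both libraries, with a library at 0 UMIs set to 3. The median was placed among the medians of 10000 random lists of equal size drawn from 20 bins of mean expression. A list is described as standing apart when it lay under the 2.5th or over the 97.5th percentile. To compare shares of cells with a UMI at equal depth, each cell was thinned to 1200 UMIs and shallower cells were left out.

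The size rule was tested on counts simulated from the WT ILC3-like levels at both libraries' totals. Of 200 genes changed in the simulation, it took 96.97% of those changed 4-fold, 58.2% of those changed 2-fold and 1.49% of those changed 1.5-fold, which is the bound of the rule itself, and it took 0 of 6021 unchanged genes at 20 CPM or more. Of 200 simulated lists of unchanged genes, 5 lay outside the percentile limits. Of 20 lists shifted by 0.5 on the log2 scale, 20 lay above them. Both simulated libraries had counting error only, which is what the interval assumes, so few false calls were fixed in advance. These values say nothing about false calls from differences between cells, mice or library preparations.

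Alternatives listed beforehand changed the cell filter, the doublet treatment, the clustering, the population, the normalization, the low-count filter, the fold threshold and the thinning depth. Alternatives chosen after seeing the data used the Ccr6-led cluster alone, ILC3-like cells without the cluster of low UMI counts, and ILC3-like cells without the clusters that came mostly from 1 library, and repeated the planned settings in ILC2-like cells. The thinned depth is the 10th percentile of UMIs per kept cell in the shallower library, rounded down. A gene of the rule, and the alternative population defined by it, is not reported here, and the counts of alternatives leave that population out. Numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used.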

Results

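Single-cell transcriptomes of sorted small-intestinal ILCs were compared between 1 library of control mice with floxed Batf and 1 library of mice in which a Plzf-driven Cre was present. BATF is a transcription factor of the AP-1 family that pairs with JUN proteins and binds DNA together with IRF4 or IRF8. ILC3s are tissue lymphocytes without antigen receptors that make IL-22. The deposited matrices held 1153 barcodes with 3138009 UMIs in the WT library and 6443 barcodes with 22004110 UMIs in the cKO library. Median depth per barcode was 1933 UMIs and 1020 genes in WT, and 3438 UMIs and 1469 genes in cKO. Median mitochondrial shares were 5.14% and 3.63%. After filtering, 731 and 5632 cells of nearly equal median depth remained. There were no replicates.

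The targeted gene, Batf, was not lower by the size rule in the library labelled cKO, and in ILC2-like cells it was lower by less than the rule asks. Batf (chromosome 12, 85686669 to 85709087) was at 88.0 CPM (95% interval 77.2 to 99.8) in all kept cells of the library labelled WT and at 107 CPM (102 to 111) in those of the library labelled cKO, a log2 ratio of 0.28 (0.086 to 0.48). In ILC3-like cells the values were 71.95 CPM (57.8 to 88.5) and 119 CPM (113 to 125), a log2 ratio of 0.72 (0.42 to 1.05). In ILC2-like cells Batf was at 107 CPM (90.3 to 125) in the library labelled WT and 68.9 CPM (61.4 to 77.0) in that labelled cKO, a log2 ratio of -0.63 (-0.92 to -0.34). None of these 3 ratios was past the size rule, but with each cell thinned to 1200 UMIs that of ILC3-like cells was, at 1.32 (0.68 to 2.04). In the ILC3-like clusters 0, 3 and 7 together Batf was higher in the library labelled cKO by the rule, at 46.3 and 116 CPM (1.33, 0.64 to 2.11). Cluster 7, with 1 cell labelled WT and 186 labelled cKO, had Batf among its 10 leading genes. It was at 418 CPM there over both libraries, against 130 and 85.7 CPM in clusters 0 and 3. Within the Ccr6-led cluster Batf was at 78.9 and 106 CPM (0.42, 0.026 to 0.84), not past the rule. At 1200 UMIs per cell, 5.93% (3.66 to 9.02) of ILC3-like cells labelled WT and 12.4% (11.4 to 13.5) of those labelled cKO had a Batf UMI, against 0 of 76 endothelial-like cells labelled cKO. In ILC2-like cells the shares ran the other way, at 13.1% (9.60 to 17.4) and 6.94% (5.45 to 8.68). Zbtb16, the gene whose promoter names the Cre, was at 41.2 and 19.99 CPM in ILC3-like cells, a log2 ratio of -1.04 (-1.48 to -0.58), not past the size rule. Its log2 ratio was -0.70 (-1.49 to 0.14) in the Ccr6-led cluster and -1.12 (-1.90 to -0.22) in clusters 0, 3 and 7 together. In all kept cells it was -0.37 (-0.78 to 0.062). The chemistry reads the 3-prime end of a transcript. A tag there may lie outside the deleted part of Batf, in which case these counts check nothing, and the libraries are named below by their labels only.

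Most cells of both libraries were ILC3-like or ILC2-like. ILC3-like cells, which had Il22, Il23r and Kit, were 54.2% (50.5 to 57.8) of the 731 cells labelled WT and 72.6% (71.4 to 73.7) of the 5632 labelled cKO. ILC2-like cells, led by Il13, Il5, Il4, Calca and Hs3st1, were 43.6% (40.01 to 47.3) and 18.1% (17.1 to 19.1). T cell-like cells, whose main cluster was led by Il17a, Cd163l1, Cd3e, Trdc and Blk, were 0.684% (0.222 to 1.59) and 5.42% (4.84 to 6.04). Endothelial-like cells were 0.274% (0.0332 to 0.985) and 1.69% (1.37 to 2.06), epithelial-like 0.547% and 0.763%, and stromal-like 0.274% and 0.373%. Cells left unnamed were 0.410% and 0.550%. No ILC1- or NK-like cell was found among 731 cells labelled WT, which allows a share of up to 0.410% by 3 counts of the total (exact interval 0 to 0.503), and 0.533% (0.360 to 0.760) of the cells labelled cKO had that name. With Batf and the genes past the size rule left out of the clustering, ILC2-like cells were 40.9% and 18.5%, and ILC3-like cells 56.9% and 74.3%. The sort gate sets such shares and is not given, and 2 sorts were compared. The T cell-like share in cKO was 0.925% with doublets kept, 1.10% with the stricter cell filter and 0% at resolution 1.5 and after centring each library. Unnamed cKO cells, 31 by the main settings, then numbered 287, 189, 679 and 321. The T cell-like name may thus have been lost there rather than the cells.

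**Figure D1:**
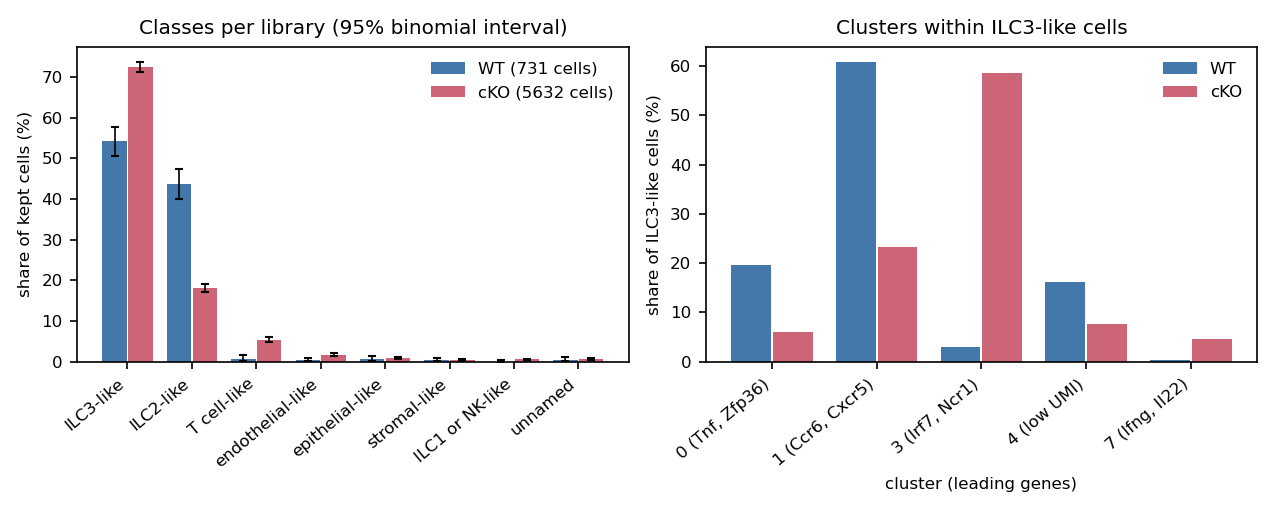
Left: share of kept cells (%) in each class for the library labelled WT (blue, 731 cells) and that labelled cKO (red, 5632 cells), with exact 95% binomial intervals. Right: share of the ILC3-like cells of each library (%) in each of 5 clusters; cluster 1 held 60.9% of those labelled WT and 23.3% of those labelled cKO, and cluster 3 held 3.03% and 58.6%.

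Different clusters made up the ILC3-like class in the 2 libraries. The Ccr6-led cluster, with Cxcr5, Odc1, Cd83 and Batf3 among its leading genes, held 241 of 396 ILC3-like cells labelled WT (60.9%) and 952 of 4087 labelled cKO (23.3%). Cluster 3, led by Irf7, Pltp, Capg and Ncr1, held 12 (3.03%) and 2397 (58.6%), and cluster 7, led by Gadd45g, Ifng, Il22 and Batf among others, held 1 and 186. A cluster that comes mostly from 1 library may be that library and no cell type. Cluster 0, led by Tnf, Zfp36 and Hspa1a, held 78 and 244 cells, and cluster 4, whose median was 1248 UMIs, held 64 and 308.

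In ILC3-like cells of the library labelled cKO, 190 genes were higher and 392 lower by the size rule, among 6227 genes at 20 CPM or more. By the interval bound nearest to no change, the genes farthest upward were Pltp, a phospholipid transfer protein (chromosome 2, 164839518 to 164857711; 10.5 and 165 CPM, log2 ratio 3.97, interval 3.20 to 4.88), Ly6a, which encodes Sca-1 (3.02, 2.52 to 3.59), and Gclm, a subunit of the enzyme that begins glutathione synthesis (2.76, 2.26 to 3.30). Lgals3, Avil, Susd2, Irf7, Traf4, Actn2, Psme2b, Ftl1-ps1 and Got1 followed, with log2 ratios between 1.91 (Traf4 and Irf7) and 2.86 (Avil). Farthest downward were the heat-shock gene Hspa1a (chromosome 17, 34969190 to 34972156; 758 and 49.5 CPM, -3.94, -4.08 to -3.79) and Cd83, an activation marker (1877 and 149 CPM, -3.65, -3.74 to -3.57). Spi1, Cdk5rap1, Hspa1b, Zfp36, Hist1h3a, Jun, Cd4, Egr1, Gucy1a1 and Hes1 followed, with log2 ratios between -4.23 (Spi1) and -2.63 (Egr1). Pltp, Irf7 and Avil were also among the 10 leading genes of cluster 3, Cd83 of the Ccr6-led cluster, and Hspa1a, Hspa1b and Zfp36 of cluster 0. Hspa1a, Hspa1b and Zfp36 were also lower within the Ccr6-led cluster (-4.02, -2.99 and -2.21) and over clusters 0, 3 and 7 together (-3.53, -2.93 and -3.37). In those pooled clusters 78 of 91 cells labelled WT were of cluster 0, which these genes lead, and 2397 of 2827 labelled cKO were of cluster 3. The pooled values may therefore follow from the mix of clusters. Of the 24 genes, Pltp, Lgals3, Avil (0.45), Susd2 (1.52) and Got1 (0.79) were not past the size rule within the Ccr6-led cluster. Pltp was at 3.49 (0.93 to 8.83) there, over 1 UMI in WT, and missed only the 20 CPM minimum, while Lgals3 had 0 and 18 UMIs. Within clusters 0, 3 and 7 together Lgals3 (1.21), Irf7 (0.81), Actn2 (1.01), Spi1, Cd4 and Gucy1a1 were not past the rule. Cd4 was at -3.18 (-4.88 to -1.11) and missed only that minimum, Spi1 had 0 UMIs in both libraries, and Gucy1a1 had 0 and 8. Psme2b and Ftl1-ps1 are near-identical copies of other genes, so their counts are uncertain. With median-of-ratios scaling the split was 246 higher and 330 lower, and 74 and 148 genes were past the rule in the Ccr6-led cluster alone.

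**Figure D2:**
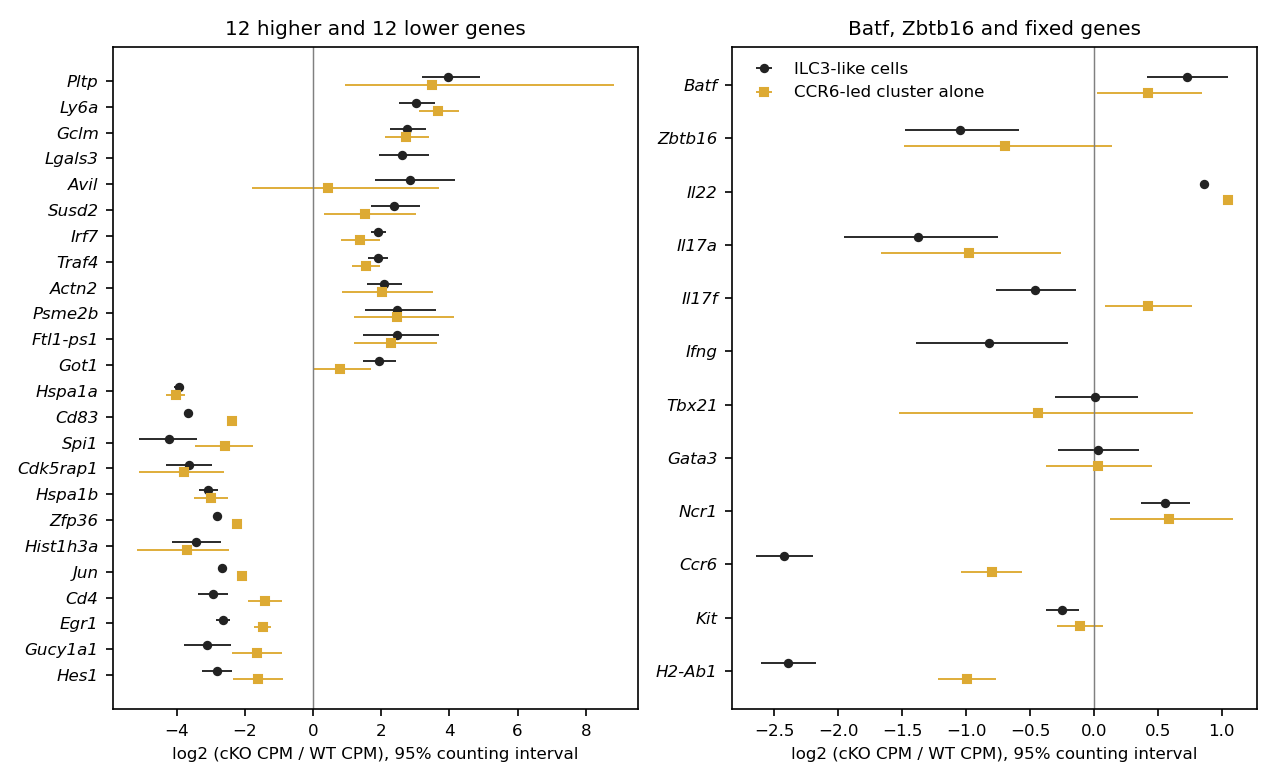
log2 ratio of CPM (library labelled cKO over that labelled WT) with 95% counting intervals for the 12 higher and 12 lower genes (left) and for Batf, Zbtb16 and 10 fixed genes (right), in ILC3-like cells (black circles) and in the Ccr6-led cluster alone (yellow squares); a gene with 0 UMIs on either side has no point. Ccr6 moves from -2.42 in the class to -0.80 in the cluster, while Hspa1a is at -3.94 and -4.02.

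Genes of the immediate early response and of dissociation stress were lower in the library labelled cKO. Of 29 measured members, 18 were lower and 0 higher by the size rule, and the list median was -1.09, at percentile 0 of the random lists. Zfp36, which destabilises cytokine mRNAs, was at 2974 and 427 CPM (-2.80), Fos at 2649 and 678 CPM (-1.97), and Jun at 4485 and 702 CPM (-2.68). The BATF, AP-1 and IRF family, which shares Fos, Fosb, Jun, Junb and Atf3 with that list, had 7 lower and 2 higher members of 18 (median -0.49, percentile 0.04). Batf3, one of the leading genes of the Ccr6-led cluster, had a log2 ratio of -1.68, Irf8 of 1.02 and Nfil3 of 0.92. Batf3 kept its call in 13 of 15 other settings, with ratios between -1.88 and -0.37. In the Ccr6-led cluster alone 6 family members were lower and 0 higher of 19 (median -0.35), so neither Irf8 nor Nfil3 was past the rule there. Clusters 0, 3 and 7 together had 5 lower and 2 higher of 18 (median -0.69).

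Genes of lymphoid tissue inducer (LTi)-type ILC3s and of MHC class II presentation were lower in the library labelled cKO over the whole ILC3-like class. Of 14 LTi-type genes 8 were lower and 1, Id2, higher (median -1.31, percentile 0). Ccr6, a receptor for CCL20, was at 201 and 37.6 CPM (-2.42, -2.64 to -2.20), Cxcr5 had a log2 ratio of -1.84, Cd4 of -2.93 and Lta of -1.46. Of 7 measured class II genes 5 were lower and 0 higher (median -1.95, percentile 0). H2-Ab1 (chromosome 17, 34257689 to 34269419) was at 215 and 41.0 CPM (-2.39, -2.60 to -2.17), H2-Eb1 had a log2 ratio of -2.48, H2-Aa of -2.15 and the invariant chain gene Cd74 of -1.95. Within the Ccr6-led cluster the medians were -0.53 for LTi-type genes (percentile 0.01) and -0.46 for class II genes (1.8), with Cd4 lower and Slc6a20a higher among the former and H2-Ab1 and H2-Eb1 lower among the latter. Within clusters 0, 3 and 7 together they were -0.44 for 13 LTi-type genes (16.0) and -0.041 for 5 class II genes (65.9), inside the random lists. Marker sums of other cell types in ILC3-like cells were 597 and 604 CPM for T cells, with 1 marker higher by the size rule, and 62.3 and 37.6 for B cells. They were 1989.7 and 2425 for myeloid cells, with 1 lower, 25.1 and 21.05 for epithelial cells, and 42.8 and 15.7 for stromal cells, with 1 lower. For ILC2s they were 366 and 505, with 2 higher and 2 lower.

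Interferon response genes stood above the random lists (median 0.67, percentile 100), with 3 of 20 members higher and 0 lower. These were Irf7 at 141 and 534 CPM (1.91, 1.70 to 2.14), Irf9 (1.95, 0.89 to 3.27) and Isg15 (0.93, 0.71 to 1.15). In the Ccr6-led cluster the median was 1.07 and 5 of 22 members were higher, and in clusters 0, 3 and 7 together it was 0.30 (percentile 99.6) with 0 of 21 past the size rule. MHC class I genes had a median of 0.29 (percentile 93.95) with 0 of 12 past the size rule, and B2m had a log2 ratio of 0.54 (0.48 to 0.61). Inhibitory and activation receptors had a median of 0.39 (percentile 99.7), with Icos (1.39), Tnfrsf9 (1.54), Klrg1 and Thy1 higher and Cd7 (-1.01) and Cd69 (-1.08) lower. That median fell within the random lists with all deposited barcodes (0.20), with the mean of CPM per cell (0.18) and in all kept cells (0.31).

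Signature genes of ILC3 function differed in both directions. Il22 (chromosome 10, 118204942 to 118210047) was higher, at 10279.8 and 18678.5 CPM (0.86, 0.84 to 0.89). Its log2 ratio was 1.05 (1.02 to 1.08) within the Ccr6-led cluster and 1.52 (1.46 to 1.59) within clusters 0, 3 and 7 together. Il22 has a near-identical copy, Iltifb, with which reads may be shared, so its level is uncertain. Il17a was lower at 24.3 and 9.36 CPM (-1.37), although it was past the size rule in only 7 of 15 other settings. Its 30 WT UMIs came from 5 of 396 cells, and without thinning the shares of cells with a UMI overlapped, at 1.26% (0.411 to 2.92) and 0.881% (0.618 to 1.22). It was -0.98 (-1.67 to -0.26) and not past the rule in the Ccr6-led cluster, had 0 and 65 UMIs in clusters 0, 3 and 7 together, and was 0.45 in all kept cells, which include the T cell-like cluster. Il7r, Ltb, Lta and Csf2 were also lower and Cxcr6 higher, and the list of 18 ILC3 effector genes had a median of -0.10 (percentile 5.6). Il17f (-0.46), Ifng (-0.82), Ncr1 (0.56), Kit (-0.25), Tbx21 (0.0095) and Gata3 (0.029) were not past the size rule. Il17f had the opposite sign within the Ccr6-led cluster (0.42, 0.086 to 0.77) and within clusters 0, 3 and 7 together (1.75, 0.19 to 4.03), the latter over 3 UMIs in WT. Without thinning, 2.20% and 2.44% of the cells of clusters 0, 3 and 7 had an Il17f UMI. NCR-positive ILC3 genes had a median of 0.28 (percentile 97.3), with Ccl4 (1.80) and Il22 higher and Xcl1 (-1.47) lower of 13. Type 1 genes had a median of 0.059 (87.9), with Ccl4 higher and Ccl5 (-2.51), Xcl1 and Tnf (-1.12) lower of 27. Within clusters 0, 3 and 7 together, which held 91 cells labelled WT and 2827 labelled cKO, both lists stood below the random lists. The NCR-positive median was -0.47 (percentile 0.36), with 1 higher and 4 lower of 13, and the type 1 median was -0.79 (percentile 0), with 0 higher and 9 lower of 28. Ifng (-2.10, -2.70 to -1.45) and Tbx21 (-1.22, -1.56 to -0.86) were lower there by the size rule, and Ncr1 had a log2 ratio of -0.40. Of these 91 cells 78 were of cluster 0, and 2397 of the 2827 were of cluster 3. Il22 was the 1 NCR-positive gene higher in those clusters and the 1 of 11 higher in the Ccr6-led cluster. Ccl4 was past the rule as higher in neither. Among 14 type 2 genes Areg (2.14), Ly6a and Klrg1 were higher and Arg1 (-1.65), Cd81 (-1.69), Csf2, Calca and Ptger2 lower, and the median of -1.10 turned to 0.029 over members of at least 20 CPM.

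**Figure D3:**
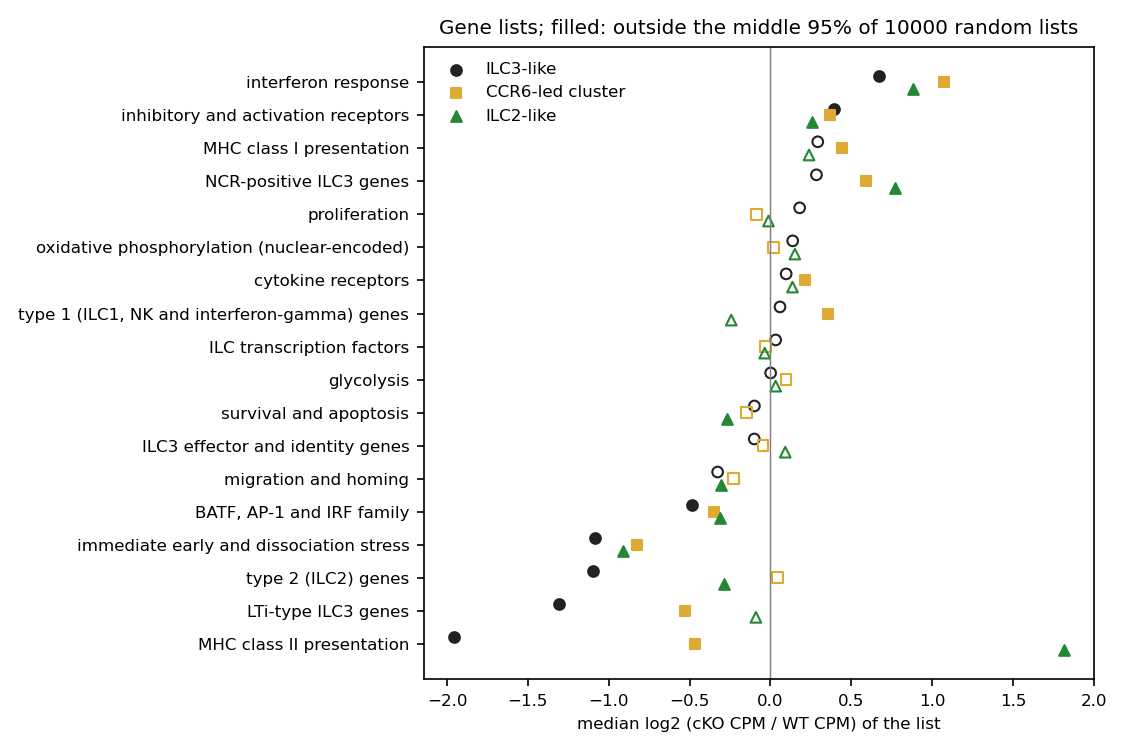
Median log2 ratio of CPM (library labelled cKO over that labelled WT) of 18 gene lists in ILC3-like cells (black circles), the Ccr6-led cluster (yellow squares) and ILC2-like cells (green triangles); filled symbols lie outside the middle 95% of 10000 expression-matched random lists. The stress list lies between -1.09 and -0.83 in all 3 populations, and the MHC class II list lies at -1.95 in ILC3-like and 1.81 in ILC2-like cells.

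The other lists stayed within the random lists in ILC3-like cells. ILC transcription factors had a median of 0.032 (percentile 65.0), with Id2, Nfil3 and Ikzf3 higher of 25 and Lef1 (-1.68), Tox2 (-1.41), Ikzf1 (-1.26) and Tcf7 among the lower. In the Ccr6-led cluster alone 0 of 24 were higher and 0 lower, and in clusters 0, 3 and 7 together 4 were higher and 3 lower of 25. Tox2 lay between -1.49 and -0.061 in 15 other settings and kept its call in 11. Migration and homing genes had a median of -0.33 (3.32), with Rgs1 (1.08) and Cxcr6 higher and 7 of 21 lower, Klf2 (-2.33) among them. Cytokine receptors had a median of 0.097 (77.8), with Tnfrsf9 and Tnfrsf1a (1.47) higher and Il10rb (-1.42), Ifngr2 and Il7r (-0.92) lower of 25. Tnfrsf1a lay between 0.65 and 2.03 in 15 other settings and kept its call in 13. The Ccr6-led cluster alone had 1 receptor higher and 2 lower of 24, and clusters 0, 3 and 7 together 1 higher and 0 lower of 25. Survival genes had a median of -0.099 (32.2), with Bcl2 (-1.27), Bcl2l1, Bcl2a1b and Gadd45b lower of 18. Proliferation genes had a median of 0.18 (96.3), with H2afz (0.99) higher of 12. Glycolysis genes had a median of 0.0013 (33.3), with Pgam1 (0.90) higher and Gapdh (-0.74) lower of 15. Of 26 nuclear genes of oxidative phosphorylation 0 were past the size rule (median 0.14, percentile 69.5).

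At equal depth and over the whole class, the shares of ILC3-like cells with an Il22, Ncr1 or Ccr6 UMI differed in the same direction as the CPM. Il22 was seen in 63.8% (58.4 to 68.9) of 337 cells labelled WT and 79.2% (77.9 to 80.5) of 3915 labelled cKO, Ncr1 in 13.9% (10.4 to 18.1) and 25.2% (23.8 to 26.6), and Ccr6 in 17.2% (13.3 to 21.7) and 4.11% (3.51 to 4.78). Within clusters the Ncr1 shares were near equal, at 29.8% (20.3 to 40.7) and 30.3% (28.6 to 32.0) in clusters 0, 3 and 7 together and 5.94% (3.20 to 9.94) and 7.07% (5.51 to 8.90) in the Ccr6-led cluster. The Il22 shares were 45.2% and 76.3% in the former and 73.5% and 86.1% in the latter, and the Ccr6 shares in the latter 23.3% and 14.99%. Clusters 0, 3 and 7 together set mostly cluster 0 of WT against mostly cluster 3 of cKO. Il22 was at 6175 CPM in cluster 0 and 13398 in cluster 3, so the mix may add to its difference there. Thinning left out 59 and 172 shallower cells. Endothelial-like cells labelled cKO, which should lack this transcript, had an Il22 UMI in 13.2% (6.49 to 22.9) of 76 cells, at a median of 2467 UMIs before thinning against 3499 in ILC3-like cells. Without thinning the ILC3-like shares were 68.2% and 85.4% for Il22, 24.2% and 49.8% for Ncr1, and 32.3% and 7.68% for Ccr6. Median genes per thinned cell were 729 and 724. Il17a was seen in 0.890% and 0.485% of cells, Il17f in 5.04% and 3.27%, Ifng in 1.48% and 0.868%, Tbx21 in 6.23% and 7.20%, Gata3 in 6.23% and 7.87%, and Zbtb16 in 4.45% and 2.53%. Il17f was seen in 6.39% and 8.46% of the Ccr6-led cluster and 1.19% and 1.46% of clusters 0, 3 and 7 together, the other way but with overlapping intervals. Tbx21 was seen in 19.0% (11.3 to 29.1) and 9.70% (8.63 to 10.9) of clusters 0, 3 and 7 together. Cells labelled WT there were mostly of cluster 0 and those labelled cKO mostly of cluster 3. Tbx21 was at 146 and 86.8 CPM in these 2 clusters, so the mix may give that difference. In the Ccr6-led cluster Tbx21 was seen in 3 of 219 and 3 of 934 cells (1.37% and 0.321%, overlapping intervals). At 1000 UMIs it was seen in 0 of 229 and 6 of 945, so no direction held.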

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

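The tests of cluster mix, handling, Batf deletion and free RNA were chosen after the results they weigh had been seen, and that of doublets was chosen before its result was seen. Batf was not lower by the size rule in the library labelled cKO, although its log2 ratio in ILC2-like cells was -0.63 (-0.92 to -0.34), so each direction here is one between labelled libraries, and library and genotype were the same split.

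MHC class II genes were lower in ILC3-like cells and higher in ILC2-like cells of the library labelled cKO. The list median was 1.81 in ILC2-like and -1.95 in ILC3-like cells. The log2 ratios in ILC2-like cells were 2.26 for H2-Ab1, 2.93 for H2-Aa, 2.84 for H2-Eb1 and 2.86 for Cd74, against -2.39, -2.15, -2.48 and -1.95 in ILC3-like cells. They were singled out because the classes went opposite ways, and the difference between the classes was not tested.

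For the ILC3-like part, a different mix between clusters as the whole cause was weighed within the Ccr6-led cluster alone. The median there was -0.46, at percentile 1.8 of the random lists, with 2 of 9 members lower, which argues against it. Ccr6 was also lower in that cluster (277 and 159 CPM). A different mix of cells inside the cluster would give the same result, and the test cannot exclude it. In clusters 0, 3 and 7 together the median of 5 members was -0.041, at percentile 65.9, with 1 lower and Cd74 at 0.42 (-0.73 to 1.88). Class II UMIs were few there, with Cd74 in 1 of 84 cells labelled WT at equal depth. That median therefore cannot show how much the mix accounts for. The median of -0.46 within the Ccr6-led cluster was smaller in size than the -1.95 over the class, so the mix may account for part of it. For the ILC2-like part, free RNA would give all cell types a like share, but at equal depth 43.0% (39.9 to 46.1) of ILC2-like cells labelled cKO had a Cd74 UMI against 1.71% (1.26 to 2.26) of the ILC3-like cells outside the Ccr6-led and low-UMI clusters. Doublets would carry more UMIs, but cells with a Cd74 UMI had 1.05 times the median UMIs of those without, and B cell and myeloid markers summed to 364 and 381 CPM. Expression by ILC2-like cells of that library stays open as a hypothesis, and a difference of genotype and one of library preparation were not separated.

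Stress genes were lower in each of the ILC3-like, Ccr6-led and ILC2-like populations of the library labelled cKO. The cluster mix alone was argued against by a median of -0.83 within the Ccr6-led cluster, at percentile 0. Different handling of the cell suspensions and an effect of Batf deletion cannot be told apart, since each library had its own suspension and its own genotype. Endothelial-, epithelial- and stromal-like cells, which are neither ILCs nor T cells, numbered 8 in the library labelled WT and 159 in that labelled cKO, too few to compare. Their list median was 1.54, at percentile 100, and does not decide between the 2.

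Other genes also went opposite ways in ILC2-like and ILC3-like cells, and the differences were not tested. Log2 ratios in ILC2-like and ILC3-like cells were -0.998 and 1.10 for Vim, -1.997 and 1.35 for Lgals1, and -0.91 and 0.94 for 4930503L19Rik. They were 0.95 and -0.86 for Arrdc4, 1.29 and -1.11 for Dgat2, 2.495 and -1.26 for Ccr7, and 1.38 and -1.28 for Ankrd33b. Cells outside the ILC classes made up part of the sorted library labelled cKO, above the limit that a count of 0 allows, with T cell-like cells at 5.42% and endothelial-like cells at 1.69%. The T cell-like share was 0.925% with doublets kept, 1.10% with the stricter cell filter and 0% in 2 other settings. Unnamed cells labelled cKO, 31 by the main settings, were 287 with doublets kept, 189 with the stricter filter, and 679 and 321 in those 2 settings. The T cell-like name may thus have been lost there rather than the cells.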

How the results depend on the processing

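The Ccr6-led cluster, ILC3-like cells without the low-UMI cluster, ILC3-like cells without the clusters mostly of 1 library, and all settings in ILC2-like cells were chosen after the data were seen. Under the alternatives 263 list medians kept their place inside or outside the percentile limits. A further 35 passed a limit they had not passed, 4 no longer passed it and 4 reversed, to the other side of the middle of the random lists. The sign of a median was not part of this count. The ILC3 effector list, for example, had a median of -0.10 by the main settings and 0.26 in all kept cells. For named genes 1265 values stayed within their counting interval, 301 left it without a change of sign in a gene past the size rule, and 7 values of genes past the rule changed sign. Batf in ILC3-like cells kept its sign under every alternative run, and left its interval with thinned cells (1.32, 0.68 to 2.04, past the size rule as higher) and in all kept cells (0.28). Where no cause is named, the cause was not tested. No paired analysis was possible because each group had 1 library.

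With all deposited barcodes, ILC3-like shares were 58.4% in the library labelled WT and 74.5% in that labelled cKO, ILC2-like shares 33.6% and 16.5%, and the T cell-like share in WT 1.65%. With at least 800 genes and under 5% mitochondrial UMIs, ILC3-like shares were 50.4% and 73.7%, ILC2-like shares 48.2% and 19.6%, and the T cell-like share in cKO 1.10%. With doublets kept, the cKO library had 19.4% ILC2-like and 0.925% T cell-like cells. At Leiden resolution 0.4 it had 74.8% ILC3-like and 3.498% T cell-like cells, and at resolution 1.5 it had 66.96% ILC3-like cells. T cell-like cells were named in 0% of both libraries at resolution 1.5 and after centring each library, where 679 and 321 cells labelled cKO stayed unnamed. Clustered without Batf and the genes past the size rule, the cKO library had 74.3% ILC3-like and 4.56% T cell-like cells.

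Genes higher in ILC3-like cells labelled cKO, 190 by the main settings, were 119 with thinned cells, which hold fewer UMIs, 317 in all kept cells, 74 in the Ccr6-led cluster, 91 without the clusters mostly of 1 library and 55 beyond 2-fold. Genes lower, 392 by the main settings, were 148 in the Ccr6-led cluster, 143 without those clusters, 814 with no minimum CPM, 227 at 50 CPM or more and 147 beyond 2-fold. In ILC2-like cells 41 genes were higher with thinned cells and 243 lower with the mean of CPM per cell. The share of higher genes among them was 39.4% by the main settings, 21.0% with thinned cells and 28.7% with the mean of CPM per cell.

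The ILC3 effector list passed the lower limit with all deposited barcodes (-0.33), thinned cells (-0.29) and the mean of CPM per cell (-0.23). NCR-positive genes passed the upper limit with all barcodes (0.32), the stricter cell filter (0.36), doublets kept (0.30), the top 8% of doublet scores removed (0.36), resolution 1.5 (0.39), centred libraries (0.31), thinned cells (0.45), the mean of CPM per cell (0.46), all kept cells (0.96), the Ccr6-led cluster (0.59), no low-UMI cluster (0.31) and members of at least 20 CPM (0.38). In clusters 0, 3 and 7 together that list stood below the lower limit instead (-0.47). Type 1 genes passed the upper limit with the stricter filter (0.29), the top doublet scores removed (0.21), resolution 0.4 (0.21), centred libraries (0.26), all kept cells (0.34), the Ccr6-led cluster (0.36) and no low-UMI cluster (0.18), and reversed to -0.40 without the clusters mostly of 1 library. Type 2 genes fell within the limits with thinned cells (-0.43) and reversed in the Ccr6-led cluster (0.044), without the clusters mostly of 1 library (0.0016) and over members of at least 20 CPM (0.029). MHC class I genes passed the upper limit in the Ccr6-led cluster (0.44) and without the clusters mostly of 1 library (0.45). Migration genes passed the lower limit with doublets kept (-0.38), resolution 1.5 (-0.36), centred libraries (-0.37), all kept cells (-0.24) and members of any CPM (-0.73). Cytokine receptors passed the upper limit with the stricter filter (0.31), in the Ccr6-led cluster (0.22), without the low-UMI cluster (0.26) and without the clusters mostly of 1 library (0.29). Proliferation genes passed it with median-of-ratios scaling (0.31) and without mitochondrial and ribosomal genes in the totals (0.24). Inhibitory and activation receptors fell within the limits with all barcodes (0.20), the mean of CPM per cell (0.18) and all kept cells (0.31).

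Without thinning, shares with a Batf UMI were 13.6% in WT and 27.3% in cKO and with an Il22 UMI 85.4% in cKO, since deeper cells show more genes. Thinned to 1000 UMIs, the Batf share in cKO was 10.9%. In all kept cells the shares were 9.17% and 11.3% for Batf and 34.4% and 63.6% for Il22. In the Ccr6-led cluster the Il22 shares were 73.5% and 86.1%.

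Single genes changed sign in a few populations. Il17f, which was not past the size rule, was 0.45 in all kept cells, 0.42 in the Ccr6-led cluster and 0.67 without the clusters mostly of 1 library. Il17a was 0.45 in all kept cells, Ccl5 was 0.34 in all kept cells and 2.94 (0.34 to 8.29) in the Ccr6-led cluster, over 1 UMI in WT, and Areg was -0.63 in all kept cells. In the Ccr6-led cluster Csf2 was 0.044 (-0.16 to 0.26) and Xcl1 3.91 (1.37 to 9.24), over 1 UMI in WT, and Cd81 was 0.0016 without the clusters mostly of 1 library. Depth limits the size rule, which took 58.2% of genes simulated with a 2-fold difference.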

Other observations

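The values for ILC2-like cells were taken after the data were seen. ILC2s are innate lymphocytes that need GATA3 and make IL-5 and IL-13. In the 319 ILC2-like cells labelled WT and 1020 labelled cKO, 99 genes were higher and 152 lower in the library labelled cKO by the size rule, among 5284 genes. Batf was lower in that library, at -0.63 (-0.92 to -0.34), and not past the rule. Nfil3, a transcription factor needed early in ILC development, was at 61.9 and 225 CPM (log2 ratio 1.86, interval 1.55 to 2.20), Gclm at 59.1 and 198 CPM (1.75), Plac8 at 100.3 and 324 CPM (1.69) and Il2rb at 196 and 405 CPM (1.05). Interferon response genes had a median of 0.88 at percentile 100, with 7 of 22 members higher, among them Ifit1 (2.37), Rtp4 (2.12), Iigp1 (1.76), Irf7 (1.36) and Irgm1 (1.33).

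Some type 2 genes were lower in ILC2-like cells of the library labelled cKO. Il1rl1, the IL-33 receptor, was at 157 and 53.5 CPM (-1.56, -1.83 to -1.29), and Nmur1, the receptor of neuromedin U, at 178 and 59.95 CPM (-1.57, -1.82 to -1.32). Csf2 was at 2864 and 882 CPM (-1.70), Arg1 at 221 and 112 CPM (-0.97), and Lpcat2 had a log2 ratio of -1.25. These were the 5 lower of 22 measured type 2 genes, 0 were higher, and the list median was -0.29 at percentile 0.06. Cytokine receptors had a median of 0.14 (percentile 89.5), with 3 higher and 1 lower of 25, and inhibitory and activation receptors one of 0.26 (98.7). Gata3 was at 1049 and 1154 CPM (0.14), and at equal depth Il13 was seen in 30.4% and 27.7% of cells and Il5 in 19.9% and 19.3%. Pla2g7 (-3.19), Ccr2 (-3.02), Anxa1 (-3.06) and Kmo (-3.41) were lower too, and Il17a had 50 and 6 UMIs, from 10 of 319 cells and 1 of 1020. Il22 was seen in 3.21% and 11.2% of ILC2-like cells at equal depth, and the 13.2% (6.49 to 22.9) in endothelial-like cells labelled cKO puts the latter at background.

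Genes past the size rule were shared between the ILC classes. Of 4963 genes at 20 CPM or more in both classes, 151 were higher in ILC3-like and 85 in ILC2-like cells, and 31 in both. Lower were 236 and 124, and 75 in both. Both comparisons used the same 2 libraries, so a shift of a whole library would give shared genes too. A further 3 were higher in ILC3-like and lower in ILC2-like cells, and 8 the reverse.

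Copies of ribosomal and ferritin genes that carry a pseudogene name stood out in ILC3-like cells, where the median of 6 copies was 1.76, with 4 higher and 1 lower in the library labelled cKO. The copies Ftl1-ps1 (2.47), Rps12-ps3 (2.84), Rpl9-ps6 (2.30) and Rpl10-ps3 (1.22) were higher and Rpl13a-ps1 (-1.74) lower, and 6 of 6 had the same sign in ILC2-like cells. A candidate explanation is that reads were shared unequally between copy and parent. The sum of copy and parent had a median of -0.0039, but the copies were at most 8.94% of that sum, so the parent fixes it and the test decides nothing. This limit of the test was recognised after its value was seen. The read lengths are not given in the sources used here, and the explanation stays open.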
